A study of Drosophila melanogaster with 4 samples.

How the data were processed

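Total RNA of 4 negative fractions from sorted Drosophila embryo cell culture was measured on 1 array each, 2 Cha-negative and 2 Gad1-negative, grouped by their labels. The deposited values are intensity, on a linear scale with 1 value per probe set. The 2%-trimmed means of the 4 columns are equal, at 500.1, so the authors' processing had scaled each array to a common level; the software is not stated in the labels used here. The probe set names are those of a 1-colour Affymetrix array. All 4 columns were matched to samples by their identifiers. The arrays' number limits the precision, and no depth applies.

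Of the 14010 probe sets, 44 were array controls, 12443 named a single gene, 327 named several and 1196 others named none. Symbols were brought up to date through Entrez gene identifiers. The 10844 genes include 1209 with more than 1 probe set, for which the probe set with the highest mean was used. No genome build is named for the probes, so no coordinates are given. Values under the 20th percentile of all values (44.9) were set to it and taken to log2. Since the trimmed means agreed within 5%, no further normalization was applied. Genes with a mean at or above the 40th percentile of all probe sets (log2 7.05, an intensity of 133) were tested, 6991 in all.

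The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, residual degrees of freedom 2), with Benjamini-Hochberg adjustment at 0.05. Differences are Gad1-negative minus Cha-negative. A gene whose group lies at the floor in both samples is given as at least the fold over the floor. The 22 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 19 lists with at least 3 tested members. Fry asks whether a list's genes move, on balance, one way and does not compare them with other genes. Agreement between samples was measured as Pearson's r across tested genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.

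The groups, tests, lists, thresholds, alternatives and the rule for named genes were chosen before the data were examined. The rule names ChAT, VAChT, ChT, Gad1, VGAT and Gat; where no gene passed in a direction, the 5 genes with the largest difference among those with an unadjusted p under 0.01; and from each list up to 3 tested members with the smallest unadjusted p. Genes outside the rule that are named in the text were chosen after their values were seen. Older gene names in the lists were matched through synonyms. After the data were seen, CPE was dropped from the neuropeptide list, because it matched by synonym to Cpes, an enzyme of sphingolipid metabolism. The 3' to 5' ratios of the array controls were set to use the floor for weak 5' signals after those signals were seen, so such ratios are lower bounds.

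The code was tested on simulated data with the spread of these arrays, in 20 simulations with 200 changed genes among 6991. Limma called 1.1% of genes changed 2-fold, 15% changed 4-fold, 62.5% changed 8-fold and 88.4% changed 16-fold, with a mean of 6 unchanged genes called. Camera with a preset correlation called a list of 10 genes shifted 2-fold in 100% of 100 simulations and an unshifted list in 6%; the simulated genes were independent of one another.

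The alternatives were quantile normalization, median centring, cyclic loess, a floor at the 10th or 30th percentile, an offset in place of the floor, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, eBayes without trend, robust eBayes, the replicate letter as a block, leaving out each sample, an adjusted p under 0.10, a 2-fold minimum, and the other list tests. A test of all probe sets above the filter other than controls was added after the data were seen. The positive fractions of these sorts were not used here.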

Results

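Transcript levels were measured on 1-colour Affymetrix arrays in total RNA from 4 samples of Drosophila melanogaster embryo cell culture. Each sample was a negative fraction, the cells that remained after fluorescence-activated sorting had taken out a class of labelled neurons. The 2 Cha-negative samples, a and b, came from cultures 3 to 5 days old in which cholinergic neurons, the cells that release acetylcholine, carried GFP. In the 2 Gad1-negative samples, a and b, the sorted neurons carried dsRed1, a red fluorescent protein driven by a 2.1 kb promoter of Gad1, the gene for the enzyme that makes GABA; their labels give no culture age. The comparison asks how the cells left by the cholinergic sort differ from those left by the Gad1 sort. The labels do not say whether a and b were separate cultures, so the p-values measure only the spread between these 4 samples. The array held 14010 probe sets, and 6991 genes lay above the intensity filter. The median probe set intensity was 248 in Cha-negative a, 219 in Cha-negative b, 213 in Gad1-negative a and 181 in Gad1-negative b. The share of probe sets under the floor of 44.9 was 15.8%, 19.0%, 20.9% and 24.3% in the same order. The number of arrays limits the precision of every value. All differences are given as Gad1-negative minus Cha-negative on the log2 scale, with the standard error (SE) of the fit and 2 samples per group.

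Samples of the same group were about as alike as samples of different groups. Across the 6991 genes, which are not independent replicates, Pearson's r was 0.731 between the Cha-negative samples and 0.715 between the Gad1-negative samples. The 4 pairs between groups had r from 0.625 to 0.766, with a mean of 0.712. More than a 2-fold gap separated the replicates in 2063 genes for Cha-negative and in 2526 genes for Gad1-negative, against 2026 to 3021 genes for the pairs between groups. Signs of RNA quality differed along the groups. The 3' to 5' intensity ratio of the GAPDH control probe sets was at least 144 in Cha-negative a and 185 in Cha-negative b, against 23.9 and 38.04 in Gad1-negative a and b, a mean ratio at least 5.42-fold higher in the Cha-negative samples. The eIF-4a ratio was at least 321 and at least 935 in Cha-negative a and b, against 230 and 77.1. The actin ratios overlapped between groups, at 59.4 and 125 against 82.0 and 107, and so did those of 18S ribosomal RNA. The geometric mean intensity of the bacterial and phage hybridisation controls was 5800, 9762, 5218 and 1959 in Cha-negative a and b and Gad1-negative a and b.

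No gene that marks the sorted neurons passed the test between the fractions. ChAT, the enzyme that makes acetylcholine, read 2000 and 594.5 in Cha-negative a and b and 590.1 and 781.1 in Gad1-negative a and b. The difference was -0.68 ± 0.69 (SE), with a 95% interval from -2.27 to 0.91 and a limma adjusted p = 0.928. Its nominal sign is opposite to a removal of ChAT-expressing cells from the Cha-negative samples, and without Cha-negative a the difference was 0.19. A further ChAT probe set, with a lower mean, read 741 and 328.5 against 447.6 and 338.2. ChT, the choline transporter, read 764.1 and 520.4 against 187.4 and 465.4, a difference of -1.09 ± 0.65 with an interval from -2.60 to 0.41. Gad1 lay under the floor in all 4 samples, at 33.4 and 29.6 against 25.3 and 18.9, so no fold was computed for it. VGAT, which loads GABA into synaptic vesicles, read 310.5 and 504.3 against 431.7 and 436.2, a difference of 0.13 ± 0.57 with an interval from -1.18 to 1.45; without Cha-negative a it was -0.22. Gat, the GABA transporter of the plasma membrane, lay under the intensity filter at 208.4 and 31.8 against 52.3 and 55.1. No probe set named VAChT alone. The marker genes therefore gave no check of which cells had been taken out, and the groups rest on the labels.

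**Figure D1:**
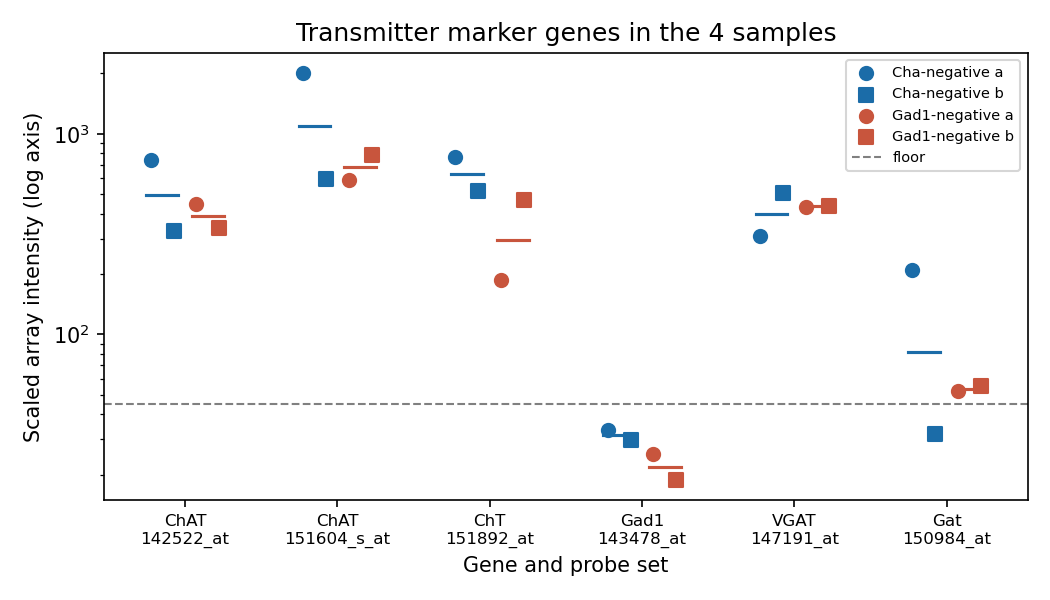
Scaled array intensity (log axis) of the transmitter marker genes, by probe set, in Cha-negative (blue) and Gad1-negative (red) samples; circles are replicate a, squares replicate b, bars the geometric mean of each group, and the dashed line the floor of 44.9. ChAT overlaps between groups, ChT reads lower in both Gad1-negative samples without passing the test, and Gad1 is under the floor in all 4 samples.

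Single genes stood far apart between the fractions, but none passed the test after adjustment over the 6991 genes. On the higher side in Gad1-negative stood E2f1, a transcription factor of S-phase entry, at 229.7 and 1112.1 against 46.2 and 39.0; with Cha-negative b at the floor the difference was at least 3.47. Drsl5, a relative of the antifungal peptide Drosomycin, read 1190.6 and 1302.9 against 370.9 and 38.6, a difference of at least 3.27, again with Cha-negative b at the floor. LManII, a lysosomal mannosidase, read 464.3 and 473.5 and lay under the floor in both Cha-negative samples, so it was at least 10.4-fold higher. CG3117 was likewise at least 10.8-fold and CG13305 at least 9.99-fold higher. On the lower side stood CG14292, at 55.8 and 55.4 against 1136.7 and 759.4 (-4.06), and Npc2e, of the Npc2 family of sterol-binding proteins, at 208.4 and 119.8 against 2311 and 1173.9 (-3.38). CG10182 differed by -3.73, Bace by -3.31 and CG4734 by -3.35, the last with Gad1-negative b at the floor, so that its size is a lower bound. These 10 genes had the largest differences among the 74 with an unadjusted p under 0.01. Limma called 0 of 6991 genes at an adjusted p under 0.05; the smallest adjusted p was 0.782. At an unadjusted p under 0.05 there were 345 genes, 146 higher and 199 lower in Gad1-negative, where chance gives 349.6, in this fit without a term for the replicate letter. Without Gad1-negative a the count was 521. Over all 4 samples with the letter as a block, 601 genes had an unadjusted p under 0.05, with 0 past adjustment. The match to chance thus depends on how the letter is treated. Of the 72 genes named by rule that have a difference, 46 moved by over 1.5 times when 1 of the samples was left out, and 7 changed sign. The groups did not overlap in 2429 genes, 34.7%, where chance gives 33.3%. An exact permutation test of 2 samples against 2 cannot give a two-sided p under 0.333. The median 95% interval reached 1.51 to either side of a gene's difference, a 2.84-fold change. In simulated data with this spread limma called 1.1% of genes changed 2-fold, 15% of those changed 4-fold and 62.5% of those changed 8-fold.

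The immune effector list stood higher in Gad1-negative by camera with a preset correlation. The heat shock and cell stress list was called as higher too, though its members went both ways. Of 10 genes tested of the immune effector list, 9 had a positive difference. Their median was 1.03 (camera adjusted p = 0.000129, and 0.604 with an estimated correlation). The positive genes include regulators of immune signalling, Rel at 0.86, cact at 0.75, nec at 0.71 and PGRP-LB at 0.67. Under the intensity filter and so untested, Def differed by 1.80, BomS2 by -1.11 and LysP by -0.55. Mtk, an antimicrobial peptide, read 6356.3 and 7887.9 against 2756.7 and 119.7 (3.62 ± 1.27). Drs, the antifungal peptide Drosomycin, read 11250.1 and 1215.8 against 853.1 and 311.9 (2.84 ± 1.03), and PGRP-SB1, a peptidoglycan recognition protein, 1372.5 and 1044.6 against 492.1 and 149.2 (2.14 ± 0.69). Of 17 heat shock and cell stress genes, 11 had a positive and 6 a negative difference. The median was 0.85 (camera adjusted p = 0.00766, and 0.604 with an estimated correlation). Negative were GstD1 at -0.71, puc at -0.60, Hsc70-3 at -0.53, kay at -0.51, Irbp18 at -0.37 and GstD2 at -0.30. The chaperone gene Hsp68 read 3671.7 and 2579.9 against 183.4 and 806.4 (3.00 ± 0.76), and Hsp26 15404.6 and 21073.2 against 1974.9 and 5111 (2.50 ± 0.68). The metallothionein MtnA read 21981.5 in Gad1-negative a and 1868.2 in Gad1-negative b, against 815.4 and 1268.9. Without Gad1-negative a the stress list was no longer called (median 0.52, camera adjusted p = 0.115). Its median was 0.25 without Cha-negative a and 0.21 with the mean of each gene's probe sets. In the same comparison the GAPDH 3' to 5' ratio was at least 5.42-fold higher in the Cha-negative samples. Among the 22 lists, no member of any passed adjusted over the list alone or over all genes tested. Camera with a preset correlation called 7 of the 19 lists that had enough genes. Camera with an estimated correlation called 0 of them, and fry called 0, with a smallest adjusted p of 0.411. For comparison, 345 of all genes tested had an unadjusted p under 0.05. The estimated correlation was 0.37 for glutamatergic, 0.30 for muscle and 0.26 for cell cycle genes, against the preset 0.01. It was 0.22 for gut, 0.20 for respiratory, 0.068 for stress and -0.108 for immune genes, on 2 residual degrees of freedom. The preset test also called the ribosomal list between the replicate letters (camera adjusted p = 1.34e-08). A call alone therefore does not tell a difference between fractions from one between arrays.

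**Figure D2:**
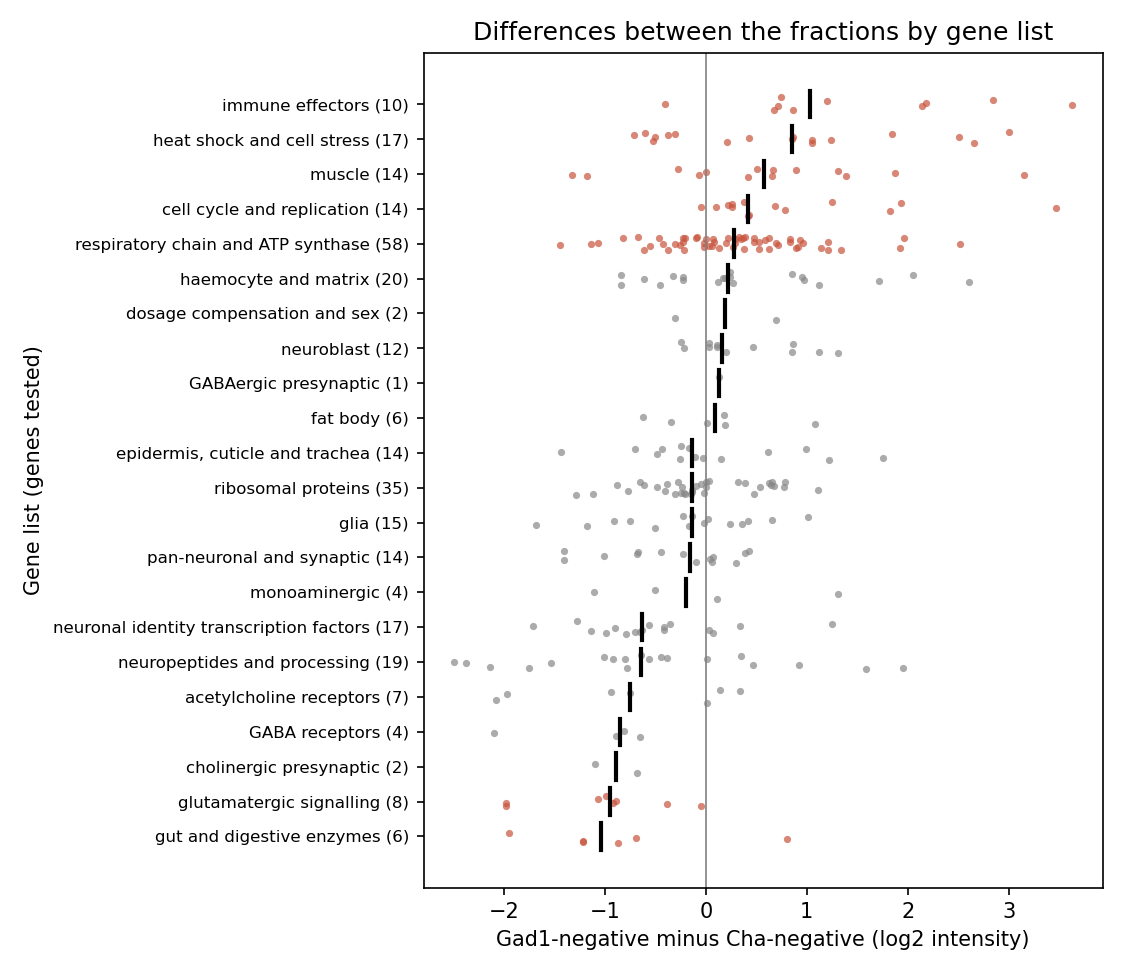
Difference between the fractions (Gad1-negative minus Cha-negative, log2 intensity) of each tested gene in the 22 lists, 1 point per gene, with the list median as a black bar and the number of genes in parentheses. The lists called by camera with a preset correlation are red; the immune effector list has the highest median, 1.03, and the gut list the lowest, -1.04.

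Genes of glutamatergic signalling stood lower in Gad1-negative by camera with a preset correlation, and the GABA and acetylcholine receptor lists did not pass. All 8 glutamatergic genes tested had a negative difference, with a median of -0.95 (camera adjusted p = 0.00690; adjusted p = 0.604 with an estimated correlation). Nmdar1, an NMDA receptor subunit, read 86.3 and 117.5 against 403.7 and 393.1 (-1.98 ± 0.69). GluClalpha, a glutamate-gated chloride channel, read 56.4 and 90.5 against 396 and 201.1 (-1.98 ± 0.85), and Nmdar2 differed by -1.07 ± 0.55. The call was lost without Cha-negative a (median -0.66, camera adjusted p = 0.103) and without Gad1-negative b (median -0.89, camera adjusted p = 0.0620). All 4 GABA receptor genes also had a negative difference, with a median of -0.85, and the list missed the threshold (camera adjusted p = 0.0510); Rdl, a GABA-gated chloride channel, read 107.1 and 589.8 against 1052 and 1110 (-2.10 ± 0.82), Grd differed by -0.81 and CG8916 by -0.89. That list passed with median centring, the offset, no intensity filter and the mean of a gene's probe sets. It also passed with eBayes without trend and with the replicate letter as a block. Over these settings camera's adjusted p for the list ran from 0.00723 to 0.0492, and from 0.545 to 0.703 with an estimated correlation. With any 1 sample left out it did not pass (camera adjusted p from 0.0629 to 0.150). The 7 genes tested of the acetylcholine receptor list had a median of -0.75 (camera adjusted p = 0.142). They include Ace, the enzyme acetylcholinesterase and not a receptor, at 0.02. Among the receptor subunits nAChRbeta2 differed by -0.94, and nAChRalpha7 and nAChRbeta1 by -2.08 and -1.97. Both nAChRalpha7 and nAChRbeta1 stood high in Cha-negative a alone, at 1076.2 and 3492. Without Cha-negative b the acetylcholine receptor list passed (camera adjusted p = 0.0375; adjusted p = 0.839 with an estimated correlation), whereas its median was -0.39 without Cha-negative a (camera adjusted p = 0.556) and -0.09 without Gad1-negative b (camera adjusted p = 0.918). Here too the GAPDH 3' to 5' ratio was at least 5.42-fold higher in the Cha-negative samples.

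The other neuronal lists did not pass as tested on all 4 samples. Of 19 neuropeptide and processing genes 13 had a negative difference, with a median of -0.64 (camera adjusted p = 0.104). Among them dimm, a transcription factor of peptidergic cells, read 176.3 and 147.8 against 490.2 and 448.7 (-1.54 ± 0.60), and the peptide gene Crz differed by -2.49 ± 0.96, whereas Ilp2, an insulin-like peptide, read 747.5 and 392.8 against 103.9 and 189.4 (1.95 ± 0.68). The median of the neuropeptide list was -0.83 without Cha-negative a and -0.49 without Cha-negative b. It was -1.26 without Gad1-negative a and -0.11 without Gad1-negative b. The 17 neuronal identity transcription factors had a median of -0.63 (camera adjusted p = 0.0537); Dll differed by -1.71, ey by -1.14 and cas by 1.25. They passed with median centring, the floor at the 30th percentile, the offset, the filter at the 60th percentile and without Gad1-negative a (camera adjusted p from 0.00788 to 0.0435; adjusted p from 0.591 to 0.823 with an estimated correlation). Without Gad1-negative b their median was -0.05 (camera adjusted p = 0.918). The 14 pan-neuronal and synaptic genes had a median of -0.16 and a camera adjusted p = 0.389. With 1 sample left out their median ran from -0.36 (without Cha-negative a) to -0.05 (without Gad1-negative a). Appl differed by -1.01, Sh by -1.41 and Shab by -1.40, the last with Gad1-negative b at the floor. Without Cha-negative a Sh differed by -0.28. The 4 monoaminergic genes went both ways (median -0.20, but 0.05 without Cha-negative b, and -1.10 over the 7 members measured with no intensity filter; camera adjusted p = 0.865), with Vmat at -1.11, ple at 1.31 and Pu at -0.50.

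By camera with a preset correlation, cell cycle genes stood higher and digestive genes lower in Gad1-negative. A called shift of muscle genes turned without 1 sample. Of 14 cell cycle and replication genes 13 had a positive difference, with a median of 0.42 (camera adjusted p = 0.00479; adjusted p = 0.604 with an estimated correlation). Besides E2f1, the replication licensing gene dpa differed by 1.83 ± 0.91, and Mcm2, another, by at least 1.94, with Cha-negative a at the floor; without that sample they differed by 0.53 and 0.99. Of 14 muscle genes 10 had a positive difference, with a median of 0.58 (camera adjusted p = 0.0371; adjusted p = 0.675 with an estimated correlation). Prm, the paramyosin of thick filaments, read 377.6 and 797.2 against 73.3 and 52.2 (3.15 ± 0.76), and Mlc2, a myosin light chain, 4097.6 and 7432.4 against 2043.9 and 1115.7 (1.87 ± 0.61), while sns, a receptor of myoblast fusion, differed by -1.18 ± 0.53. Of 6 gut and digestive enzyme genes 5 had a negative difference, with a median of -1.04 (camera adjusted p = 0.0371; adjusted p = 0.604 with an estimated correlation); the protease Jon65Aiv read 156.7 and 319.1 against 413.1 and 1800.9 (-1.95 ± 0.80), Mal-A1 differed by -1.22 and Mur18B by -1.21. The cell cycle call was lost without Gad1-negative a (median 0.25, camera adjusted p = 0.368), and its median was 1.16 without Gad1-negative b. The muscle call was lost without Cha-negative b, where the median turned to -0.26 (camera adjusted p = 0.717), and without Gad1-negative b (median 0.28, camera adjusted p = 0.294); without Cha-negative a the median was 0.96. The gut call was lost without Cha-negative b (median -0.84, camera adjusted p = 0.434) and without Gad1-negative b (median -0.57, camera adjusted p = 0.294), and with no intensity filter the 12 gut genes had a median of -0.60 (camera adjusted p = 0.114). The difference of at least 5.42-fold in the GAPDH 3' to 5' ratio lay along the same groups.

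The remaining cell type lists did not pass on all 4 samples. The 12 neuroblast genes had a median of 0.16 (camera adjusted p = 0.103), with the neuroblast genes mira at 1.31 ± 0.59, wor at 1.12 ± 0.57 and nerfin-1 at 0.86. The 20 haemocyte and matrix genes had a median of 0.21 (camera adjusted p = 0.111). Ndg, the basement membrane protein nidogen, read 344.1 and 392.4 against 76.6 and 47.6 (2.60 ± 0.80); vkg differed by 1.72 and SPARC by 2.06, values that became 0.36 and -0.18 without Cha-negative b. That list turned to lower without the same sample (median -0.28, camera adjusted p = 0.773), and its median was also -0.28 without Gad1-negative a (camera adjusted p = 0.977). It passed as higher without Cha-negative a (camera adjusted p = 0.000306; adjusted p = 0.638 with an estimated correlation) and without Gad1-negative b (camera adjusted p = 0.0167; adjusted p = 0.965 with an estimated correlation). The neuroblast list passed without Cha-negative a (median 0.66, camera adjusted p = 0.0270; adjusted p = 0.638 with an estimated correlation) and had a camera adjusted p = 0.706 without Cha-negative b; its median was 0.72 without Gad1-negative b, and 0.32 and 0.34 after quantile and loess normalization. The 15 glial genes had a median of -0.14 (camera adjusted p = 0.726), which became positive under quantile and loess normalization, with the filter at the 60th percentile and without Cha-negative b; wrapper differed by -1.68, NetB by -1.18 and nrv2 by 1.02, but nrv2 by 0.089 without Gad1-negative a and wrapper by -0.85 without Cha-negative a. The 14 genes of epidermis, cuticle and trachea had a median of -0.14, a mean of 0.06, camera's direction up and fry's down (camera adjusted p = 0.865); sinu differed by at least 1.76, with Cha-negative b at the floor, TwdlT by -1.44 and verm by 0.99. The 6 fat body genes had a median of 0.09 (camera adjusted p = 0.733), which was 0.66 without Cha-negative a and -1.02 without Cha-negative b, with FASN1 at 1.08, Ser7 at -0.63 and apolpp at -0.35; apolpp was 0.60 without Cha-negative a and 0.45 without Gad1-negative a.

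The respiratory chain list was called as slightly higher in Gad1-negative, a shift that was absent without Cha-negative a or without Gad1-negative b. Of 58 respiratory chain and ATP synthase genes 37 had a positive difference, with a median of 0.28 (camera adjusted p = 0.0245; adjusted p = 0.675 with an estimated correlation). ND-B18 differed by 1.96, ATPsynB by 1.92 ± 0.68 and ATPsynF by 1.34 ± 0.51, the last at 2639.3 and 2864.2 against 1130 and 1040. This call was lost after quantile normalization (camera adjusted p = 0.0964), after cyclic loess (0.0897) and with no intensity filter (0.0662). It was also lost without Cha-negative a (median 0.0021, camera adjusted p = 0.482) and without Gad1-negative b (median -0.026, camera adjusted p = 0.918). The GAPDH 3' to 5' ratio was at least 5.42-fold higher in the Cha-negative samples in this comparison as well. Between the replicate letters the respiratory list differed more than between the fractions. In b, 46 of its 58 genes were higher than in a, with a median of 0.48. The 35 ribosomal protein genes had a median of -0.14 and a mean of -0.05, camera's direction was up and fry's down (camera adjusted p = 0.879), and camera's direction turned under quantile, median and loess normalization. Ribosomal genes too read lower in a than in b (median a minus b -0.96 in Cha-negative and -0.90 in Gad1-negative). Leaving out 1 sample, which unbalances the letters, called the ribosomal list in opposite directions. It was lower without Cha-negative a (median -0.58, camera adjusted p = 0.0450; adjusted p = 0.834 with an estimated correlation) and higher without Gad1-negative a (median 0.43, camera adjusted p = 0.0497; adjusted p = 0.830 with an estimated correlation). RpL24-like differed by 1.11, RpL37-2 by -0.88 and RpS20 by -1.11. Of the dosage compensation and sex genes, tra differed by 0.69 and Sxl by -0.31, neither past the test; tra was -0.03 without Gad1-negative a and Sxl 0.01 without Cha-negative a.

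**Figure D3:**
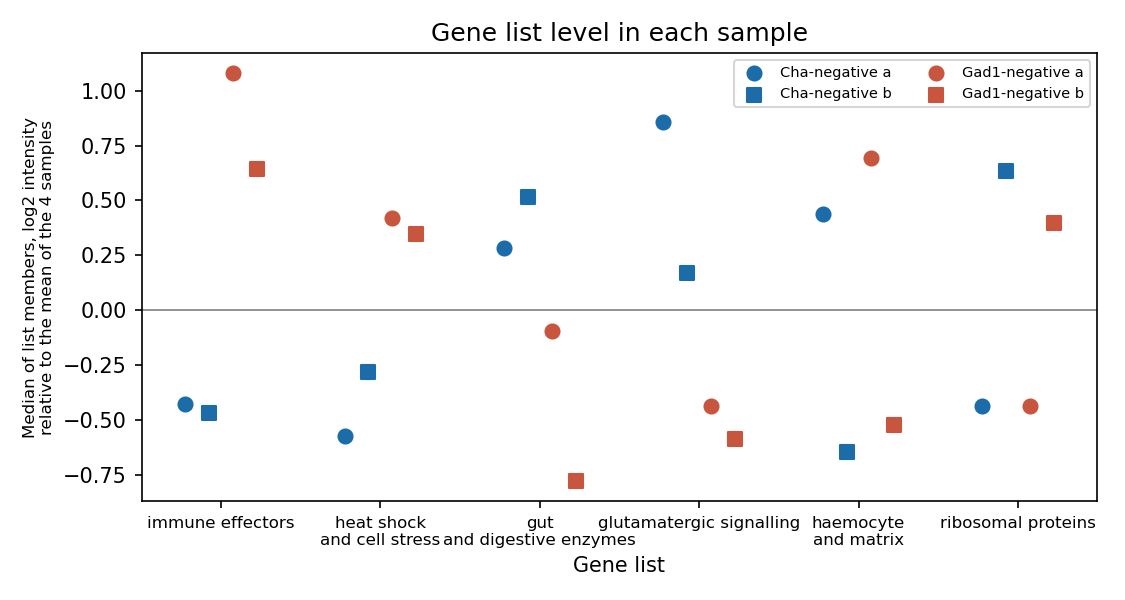
Median level of the members of 6 gene lists in each sample (log2 intensity relative to each gene's mean over the 4 samples), with Cha-negative in blue, Gad1-negative in red, circles for replicate a and squares for replicate b. The immune, stress, gut and glutamatergic lists part by group, and the haemocyte and ribosomal lists part by replicate letter.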

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

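The test of all probe sets was chosen after the results were seen; the other alternatives were planned. The count of 0 genes at an adjusted p under 0.05 by limma held in every alternative run, including an adjusted p under 0.10, a 2-fold minimum, each sample left out and the replicate letter as a block; the smallest adjusted p in any of them was 0.102, without Cha-negative a. Over all 8402 probe sets above the filter, array controls included, it was also 0, with 422 at an unadjusted p under 0.05. The count at an unadjusted p under 0.05, 345 as reported, was 717 with no filter, where more genes were tested, 213 with the filter at the 60th percentile, where fewer were, and 601 with the replicate block; with 1 sample left out it ran from 256 to 521, the highest without Gad1-negative a. A left-out sample leaves a lone sample in its group, assumed to vary like the other group. Median centring, which shifts all genes alike, moved the median difference of all genes from -0.04 to 0.20, and the other normalizations moved it to at most 0.05. Low signal limits Gad1 and other genes near the floor.

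The number of lists called was 7 as reported, 4 with the filter at the 60th percentile, 0 with camera's estimated correlation, 0 with fry, and from 4 to 9 with 1 sample left out. The cause was not tested for the changes listed here except where fewer genes or samples were used. With the estimated correlation the adjusted p was 0.604 for the glutamatergic, cell cycle, gut, heat shock and immune lists and 0.675 for the muscle and respiratory lists. With fry it was 0.464 for glutamatergic, 0.587 for cell cycle, 0.601 for muscle, 0.566 for gut, 0.565 for heat shock, 0.411 for immune and 0.702 for respiratory genes. With the filter at the 60th percentile camera's adjusted p was 0.0650 for the glutamatergic, muscle and gut lists and 0.0682 for cell cycle. With no filter it was 0.148 for muscle, 0.114 for gut and 0.0662 for respiratory genes, which had 0.0964 after quantile normalization and 0.0897 after cyclic loess. With 1 sample left out camera's adjusted p ran from 0.00553 to 0.103 for glutamatergic, 7.12e-05 to 0.368 for cell cycle, 0.000306 to 0.717 for muscle, 0.00901 to 0.434 for gut, 0.00148 to 0.115 for heat shock and 0.000466 to 0.918 for respiratory genes.

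Among called lists the median turned for muscle, to -0.26 without Cha-negative b, and for respiratory genes, to -0.026 without Gad1-negative b, while camera's direction stayed up. The GABA receptor list, not called as reported, passed with the replicate block (camera adjusted p = 0.0492; adjusted p = 0.703 with an estimated correlation). Camera's or fry's direction turned only in lists that had not been called, over the alternatives run. They were the monoaminergic list with the replicate block (adjusted p = 0.970), glia (0.952) and epidermis (0.990) with the filter at the 60th percentile, epidermis with fry (0.952), and ribosomal proteins after quantile normalization (0.721), median centring (0.977), cyclic loess (0.641), with the floor at the 10th percentile or the offset (0.949 each) and with fry (0.962). Some lists turned by camera with 1 sample left out. Over all such fits, turned or not, their adjusted p ran from 0.532 to 0.885 (monoaminergic) and 0.000306 to 0.977 (haemocyte and matrix). It ran from 0.103 to 0.918 (fat body), 0.711 to 0.918 (epidermis) and 0.0450 to 0.0629 (ribosomal proteins). Except for ribosomal proteins, the lowest value of each list came from a fit that had kept its direction. Haemocyte and matrix genes turned only without Cha-negative b, to a median of -0.28. Ribosomal proteins turned to lower without Cha-negative a (0.0450, median -0.58) and without Gad1-negative b (median -0.49). The log2 differences that changed sign ran from -1.56 to 0.19 for ChAT, -0.22 to 0.48 for VGAT, -1.96 to 0.26 for Gat, -0.18 to 4.29 for SPARC, -1.29 to 0.60 for apolpp, -0.035 to 1.42 for tra and -0.62 to 0.0053 for Sxl. Pearson's r with no filter was 0.832 within Cha-negative, 0.840 within Gad1-negative and 0.826 between groups on average, and 0.652 within Gad1-negative with the filter at the 60th percentile.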

Other observations

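The tests of explanations for the immune list, of a single library for the gut list, of a shared batch and of the gene lists for the replicate letters, and of probe sets that name no single gene were chosen after the results were seen, though the fits with 1 sample left out or an estimated correlation that they draw on were planned. Single genes of the lists differed widely between replicates. In Cha-negative b the peptide genes Dh31, AstC and NPF read 26438, 11061 and 12106, against 3539, 1883 and 963.5 in Cha-negative a and at most 2396.5, 1523.7 and 1329.2 in the Gad1-negative samples. The metallothionein MtnB read 6717 in Gad1-negative a and 79.3 in Gad1-negative b, a gap of 84.7-fold, beside 218 and 190.1 in the Cha-negative samples. Mtk read 119.7 in Cha-negative b and 2757 in Cha-negative a, a 23.0-fold gap, and DptB, another antimicrobial peptide, 770 against 13513. SPARC parted the same samples 22.1-fold. The pan-neuronal gene elav, which encodes an RNA-binding protein, read 67.2 and 909.3 in Gad1-negative a and b.

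Several neuronal genes lay under the intensity filter and so outside the comparison. The transcription factor gene fru read 389.4 and 245.5 in Cha-negative a and b and lay under the floor in both Gad1-negative samples, at 39.2 and 35.0. GABA-B-R1, a metabotropic GABA receptor, read 81.9 and 79.1 against 24.4 and 21.1, and the dopamine transporter gene DAT 211.6 and 193.7 against 50 and 84.7. In the other direction nSyb, a synaptic vesicle protein, lay under the floor in both Cha-negative samples and read 126.7 and 296.1 in Gad1-negative a and b. These genes were chosen after their values were seen. With no filter limma called 0 of 10844 genes, with 717 at an unadjusted p under 0.05. Of 969 probe sets above the filter that name no single gene, array controls included, limma called 0, with 64 at an unadjusted p under 0.05.

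The immune effector list stood higher in Gad1-negative with a median of 1.03. A single library does not account for that median, which was at least 0.85 with any 1 sample left out. In these fits camera still called the list with the preset correlation, but not with an estimated correlation. The size for single members did lean on 1 sample. With 1 sample left out the difference ran from 1.36 to 5.89 for Mtk and from 1.24 to 4.45 for Drs. Whether members vary together between replicates was not decided: the estimated correlation was negative, at -0.108, but rests on 2 residual degrees of freedom, and with estimated correlations none of the 19 lists had an adjusted p under 0.604. RNA with a different 3' bias cannot be told apart from the groups, because the GAPDH 3' to 5' ratio differed at least 5.42-fold along them and that of eIF-4a also parted them, although the actin and 18S ratios overlapped. A difference in culture age or in the cells left by each sort was untested.

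Gut genes stood higher in Cha-negative, and a candidate explanation is more gut-like cells there, which neither sort would remove. In 15 gut gene families, 29 of 41 genes that are not on the fixed list were lower in Gad1-negative, with a median of -0.51. Camera gave p = 0.0178 with the preset correlation and p = 0.107 with an estimated correlation. At an unadjusted p under 0.05, 5 were lower and 2 higher, Cht5 by 2.01 and Npc2g by 3.04. The Jon, Try, Lys, Mal and Mur genes among the 41 share families with members of the fixed list. For those families the test is not independent of that list, and all genes were read on the same arrays. The families were chosen after the genes with the smallest p had been seen, which prompted some of them; those genes were left out, but Lys genes resemble the fixed list's LysB, cross-hybridisation between such relatives was not tested, and the obst and Cht families also serve cuticle. Among the most abundant, LysS read 4936 and 12166 against 1899 and 490.8, and Peritrophin-15a 6423 and 14437 against 2072 and 8435, while obst-E read 2300.5 and 784.9 against 894.5 and 5542.5. A single library carrying the fixed list's shift stays open: with 1 sample left out the median stayed between -1.47 and -0.57, the latter without Gad1-negative b with a standard error over members of 0.51, and the call was lost there and without Cha-negative b (camera adjusted p = 0.294 and 0.434).

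Samples of the same letter deviated together: across 6991 genes the a minus b differences of both groups had r = 0.251 and Spearman's rho = 0.282, and a against b gave 622 genes at an unadjusted p under 0.05, against 345 for the labelled groups and 125 for the crossed split, with 0 genes past limma's adjusted p in each. In b, 32 of 35 ribosomal protein genes were higher (median 0.95, camera adjusted p = 1.34e-08; adjusted p = 0.362 with an estimated correlation; fry adjusted p = 0.0266), 46 of 58 respiratory genes were higher (camera adjusted p = 0.000328; adjusted p = 0.603 with an estimated correlation), and 19 of 20 haemocyte and matrix genes were lower (median -0.94, camera adjusted p = 0.00132; adjusted p = 0.532 with an estimated correlation). Different intensity distributions and signal near the floor do not account for it, since r was 0.241 after quantile normalization and 0.275 among genes above the 60th percentile. A day, culture or array batch shared by each letter may account for r = 0.251 and cannot be told apart from other sources, because the labels give no day or batch. No biological explanation was tested, since the design gives the letters none.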
